A study of Homo sapiens with 6 samples.

How the data were processed

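Total RNA of NCI-H520 cells grown with 15% fetal bovine serum was extracted with TRIzol, and 1.5 µg went into libraries made with an ABclonal Fast RNA-seq kit, per the labels' protocols. The 6 samples fall into PBS and 2 µM cisplatin groups of 3, both at 48 h, per the labels. One table per sample was used. The authors deposited expected counts per gene, which need not be whole, together with TPM values (transcript abundances scaled to a fixed total per sample) and transcript and effective lengths; the columns are those of an RSEM table, per the file headers, and the counts are not normalized. The FPKM values that the authors deposited beside them, scaled by transcript length and by the fragments of each sample per the file headers, were not used here. Alignment used STAR 2.7.9 and the GRCh38 (hg38) genome, per the submitters' processing notes. The version of the quantifier, its annotation release, the use of strand and any poly(A) selection are not given in the sources used here. Reads of a gene and of an overlapping antisense gene therefore cannot be told apart.

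The files list 61552 genes. Symbols came from a table of gene identifiers, which named 61399 of them, and positions, biotypes and transcript GC content from GENCODE 29, which is on the same build and gave 58352 positions; the files' own annotation may differ from it. Exonic overlaps of the named genes with other genes were computed from the same annotation, and 13 of 152 named genes share at least 10% of their exonic bases with a tested gene.

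Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr with a count minimum of 10 and a total of 15, which left 15063 genes, TMM scaling, and the quasi-likelihood test on the group alone. P-values were adjusted by Benjamini-Hochberg, and a gene was called under 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM are counts scaled by the TMM-adjusted library size. Totals of 9121180 to 16724285 counts per library set the precision. The 95% intervals of fold changes rest on the quasi-likelihood standard error and so include the spread between libraries, while the floor of 3 counts covers counting error only. No pair of libraries held the same counts, and within groups the chi-square per degree of freedom ran from 2.99 to 20.6.

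Gene lists (29, with 763 entries, all matched by symbol) were fixed before the data were examined and tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. None of the 6 lists that passed held with an estimated correlation. For interferon-stimulated genes and fibroblast markers that estimate, 0.00427 and -0.022, was below the preset 0.01. Correlation among members therefore does not explain the loss of these lists, and the variant is stricter in more than the correlation. The lists reported cover 3 groups of DNA repair and checkpoint genes, G1/S and G2/M genes, histones, apoptosis, stress, NRF2, metallothioneins, platinum transport, squamous, stem cell and keratinocyte genes, epithelial-mesenchymal transition, NF-kB, interferon, immediate early, coactivator, Notch and Wnt, cholesterol, hypoxia, mitochondrial and ribosomal genes, and markers of 4 other cell types.

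The genes named were chosen by a rule written beforehand: 12 fixed genes whatever their values; the 10 largest changes in each direction among called protein-coding genes with a mean of at least 5 CPM and no overlap between the groups; and from each list up to 3 called members with the smallest adjusted p in each direction or, with none called, the 2 most abundant. CD3EAP, USP37 and PDZD8 were named later for their overlap with named genes. Some genes that the rule takes, and 1 of the lists, are not reported here. Gene length was the annotated genomic span and the deposited transcript length, averaged over the libraries.

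The analysis was tested on simulated counts for the 15063 genes of the comparison, with 200 changed genes in each of 5 runs. It recovered 61.8% of genes changed 1.5-fold, 86.7% at 2-fold and 98.8% at 4-fold. With each gene's own estimated dispersion, 9.04% of calls were false on average (at most 12.7%), above the nominal 5%; with the trended dispersion the share was 4.87%. The larger share means that the adjusted p may be somewhat too small for genes near the threshold. The simulation changed 200 genes, whereas 5752 were called in the real comparison, so these shares need not carry over to it. With no change simulated, 0 genes were called, and a length slope of -0.15 was recovered as -0.148.

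Alternatives fixed beforehand were RLE, upper quartile and total count scaling, no low-count filter or one of 50 counts in 3 samples, the replicate number as a block, leaving out each library, protein-coding nuclear genes only, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1), glmTreat against 1.5-fold, and camera with an estimated correlation or fry for the lists. Corrections for transcript length, and for length and GC content, as splines with 5 degrees of freedom fitted per library, were added after seeing the data. No sample was left out.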

Results

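RNA sequencing was carried out on NCI-H520, an established human lung squamous cell carcinoma line, after 48 h with phosphate-buffered saline (PBS) or with 2 µM cisplatin, a platinum drug that crosslinks DNA. Each group held 3 libraries. The series title concerns the transcription factor SOX2 and resistance to chemotherapy in this tumour type, and the comparison asks how gene expression in these cells differs after the drug. Expected counts assigned to genes totalled 9121180, 15589897 and 14066008 in the PBS libraries and 9925328, 11165041 and 16724285 in the cisplatin libraries. Mitochondrially encoded genes took 4.99% ± 0.971 of the counts under PBS (SD, n = 3) and 3.65% ± 0.443 under cisplatin. The first principal component of log2 CPM (counts scaled by library size) held 58.9% of the variance and separated the 3 PBS from the 3 cisplatin libraries. The labels do not say that the replicates are separate cultures, so the p-values measure only the spread between these samples, which may be technical.

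The libraries of cisplatin-treated NCI-H520 cells held less mRNA of replication-dependent histones, the proteins that package newly made DNA: 43 of 48 tested genes fell, with a median log2 fold change of -1.72. Genes of G2 phase and mitosis moved the other way, with 24 of 32 higher, among them the mitotic cyclin CCNB1 at 158 ± 3.1 CPM under PBS and 283 ± 8.87 under cisplatin (SD, n = 3). Interferon-stimulated genes were higher in 14 of 22 cases, led by the antiviral enzyme OAS1, which rose 3.67-fold. The cell cycle inhibitor CDKN1A rose 2.27-fold while the ubiquitin ligase MDM2 fell by 0.46 on the log2 scale. SOX2 mRNA stood at 309 ± 24.2 CPM under PBS and 323 ± 26.7 CPM under cisplatin, a difference smaller than the spread between replicates.

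In all, 5752 of 15063 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2851 higher and 2901 lower under cisplatin. At least a 2-fold change was seen in 852 of them, 522 higher and 330 lower. That number was 302 with a stricter low-count filter, which still tests 11767 genes, and 248 on TPM. It therefore rests largely on genes with low counts. All 3 cisplatin libraries lay on one side of all 3 PBS libraries in 7480 of the 15063 tested genes, an arrangement that chance gives to 10% of genes, and 5558 of these were called. The count of called genes depends on the size of change asked for, since 481 genes passed a test against a 1.5-fold change. It also depends on the scale and tool: limma on log2(TPM + 1), which asks for no larger change, called 2861. On that scale, limma did not call the kinase ATM (-0.15, adjusted p = 0.644), SLC2A1 (0.11, 0.656), COL1A1 (0.28, 0.256), BMF (0.28, 0.288) or FAN1 (-0.34, 0.156), all called by edgeR. These are the highest adjusted p over the alternatives, the lowest being 5.3e-08, 1.0e-05, 1.2e-08, 6.1e-04 and 4.4e-06 in the same order, and the cause was not tested.

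SOX2 (ENSG00000181449; chromosome 3, 181711924 to 181714436 in GRCh38) had a log2 fold change of 0.06 ± 0.08 (SE; edgeR adjusted p = 0.583), and the 95% interval of its fold change ran from 0.921 to 1.19. Its counts were 2520 to 4844 per PBS library and 3028 to 5872 per cisplatin library. TP63, the squamous transcription factor that partners SOX2, had 0, 3 and 1 counts in the PBS libraries and 1, 2 and 2 in the cisplatin libraries, at or under the floor of 3 counts, so no fold is given. The basal keratin KRT5 was near 5 CPM in both groups (5.42 ± 0.811 and 4.72 ± 0.914), with a log2 fold change of -0.21 and an edgeR adjusted p of 0.416.

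**Figure D1:**
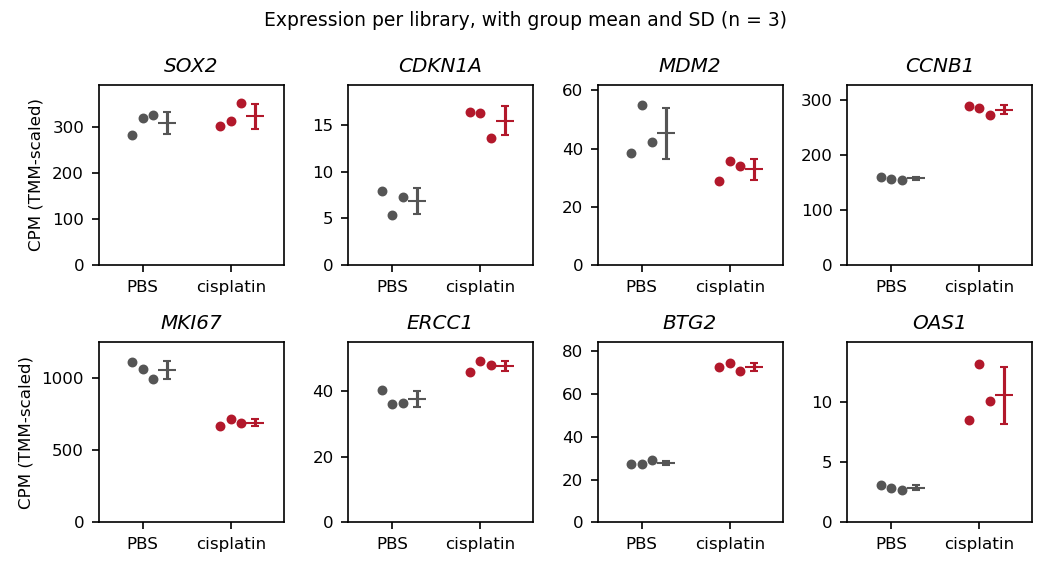
TMM-scaled CPM of 8 genes in each library (points, 3 per group), with the group mean and SD beside them, and every axis starting at 0. SOX2 overlaps between the groups, whereas CCNB1 lies near 158 CPM in the PBS libraries and near 283 CPM in the cisplatin libraries.

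Among the damage-response genes fixed in advance, CDKN1A (chromosome 6, 36676460 to 36687339) rose from 6.86 ± 1.36 to 15.4 ± 1.55 CPM, with a log2 fold change of 1.18 ± 0.16 (SE) and an edgeR adjusted p of 1.8e-04. MDM2 had 45.3 ± 8.75 CPM under PBS and 33.0 ± 3.58 CPM under cisplatin (log2 fold change -0.46 ± 0.13, edgeR adjusted p = 0.0145). That edgeR call was lost without PBS replicate 2 (adjusted p = 0.0578), without cisplatin replicate 1 (0.0716) and after a correction for transcript length chosen after the data were seen (-0.21, adjusted p = 0.192); over all alternatives the adjusted p ran from 1.7e-04 to 0.268. TP73, a transcription factor, had a log2 fold change of -0.30 ± 0.13 (edgeR adjusted p = 0.0763). Without PBS replicate 2, TP73 passed in edgeR (-0.40, adjusted p = 0.0177), and over the alternatives its adjusted p ran from there to 0.399.

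The proliferation antigen MKI67 fell by 0.61 ± 0.07 on the log2 scale, from 1055 ± 59.5 to 691 ± 24.2 CPM (edgeR adjusted p = 9.3e-05), and by 0.24 after the length correction. MYC fell by 0.25 ± 0.08 (edgeR adjusted p = 0.0259), a call that was lost when any library except PBS replicate 2 was left out (adjusted p = 0.0733 without PBS replicate 1, 0.0777 without PBS replicate 3, and 0.0575, 0.0885 and 0.0899 without cisplatin replicates 1, 2 and 3). Over all alternatives the adjusted p of MYC ran from 9.3e-05 to 0.108. The excision repair nuclease subunit ERCC1 rose by 0.35 ± 0.08 (edgeR adjusted p = 0.00659). It was not called after the length correction (0.20, edgeR adjusted p = 0.0743, with 0.00444 to 0.206 over the alternatives), and 28.6% of its exonic bases are shared with CD3EAP on the opposite strand, which fell by 0.77. The copper transporter SLC31A1, which also carries platinum, had a log2 fold change of -0.11 ± 0.08 (edgeR adjusted p = 0.290). The efflux pump ABCC2 rose by 0.25 ± 0.08 (edgeR adjusted p = 0.0195), and was not called without cisplatin replicate 1 (adjusted p = 0.0911, with 4.5e-04 to 0.617 over the alternatives).

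Among called protein-coding genes with a mean of at least 5 CPM and no overlap between the groups, the 10 with the largest increases included VIL1, TENT5C, SLC18A2, C11orf52, OAS1, IL22RA1, PIGZ, GFRA3 and MYO7A, between 3.15-fold and 4.40-fold higher. TENT5C, a poly(A) polymerase, went from 23.0 ± 1.11 to 95.7 ± 4.28 CPM (log2 fold change 2.05 ± 0.08, edgeR adjusted p = 7.6e-08). GFRA3, a co-receptor of the RET kinase, went from 22.6 ± 1.04 to 76.4 ± 2.39 CPM (edgeR adjusted p = 1.7e-07). VIL1 and SLC18A2 share 44.0% and 52.0% of their exonic bases with USP37 and PDZD8 on the opposite strand, genes that fell, and C11orf52 shares 73.4% with a read-through gene, so these values are less certain. Below, FAN1, RNF43, TGFB2 and VIM also share at least 10% of their exonic bases with another tested gene and are uncertain for the same reason. Under the same limits all of the 10 largest decreases were histone genes, from H2BC18 (log2 fold change -2.75 ± 0.21, edgeR adjusted p = 6.1e-06) to H2BC5 (-1.89 ± 0.19, adjusted p = 3.3e-05).

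Of the replication-dependent histone genes, 43 of 48 tested fell and the other 5 did not pass (1 higher and 44 lower when adjusted over the list alone), and camera placed the list below the other genes (Benjamini-Hochberg adjusted p = 1.3e-17). The list was not called when its correlation was estimated (adjusted p = 0.503 with an estimated correlation). The linker histone H1-4 went from 16.1 ± 4.04 to 3.76 ± 0.743 CPM. Reads of near-identical histone copies can be divided among them by the quantifier, so single members are uncertain. Summed over the list, histone mRNA stood at 484 ± 128 CPM under PBS and 153 ± 28.2 CPM under cisplatin (SD, n = 3), 3.17-fold lower, with every cisplatin library below every PBS library.

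Among G2/M and mitosis genes, 24 of 32 rose and 1 fell, and 25 rose and 1 fell when adjusted over the list alone (camera adjusted p = 8.2e-09, and adjusted p = 0.470 with an estimated correlation). The ubiquitin-conjugating enzyme UBE2C of the anaphase-promoting complex rose by 0.95 ± 0.07 on the log2 scale, the phosphatase CDC25B that activates mitotic kinases by 1.06 ± 0.08 and CCNB1 by 0.84 ± 0.07. MKI67 was the member that fell. In the list of G1/S and DNA replication genes, 1 of 32 rose and 11 fell (2 and 13 adjusted over the list alone; camera adjusted p = 0.0574, not passed). Camera called it without PBS replicate 2 (adjusted p = 0.0440) and without cisplatin replicate 1 (0.0417), with 0.0320 to 0.528 in camera over the alternatives. The helicase subunit MCM4 fell by 0.52, the methylation maintenance factor UHRF1 by 0.58 and the replication factor MCM10 by 0.41, while the thymidine kinase TK1 rose by 0.31 and was not called by edgeR after the length correction (adjusted p = 0.137, with 0.00255 to 0.418 over the alternatives).

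**Figure D2:**
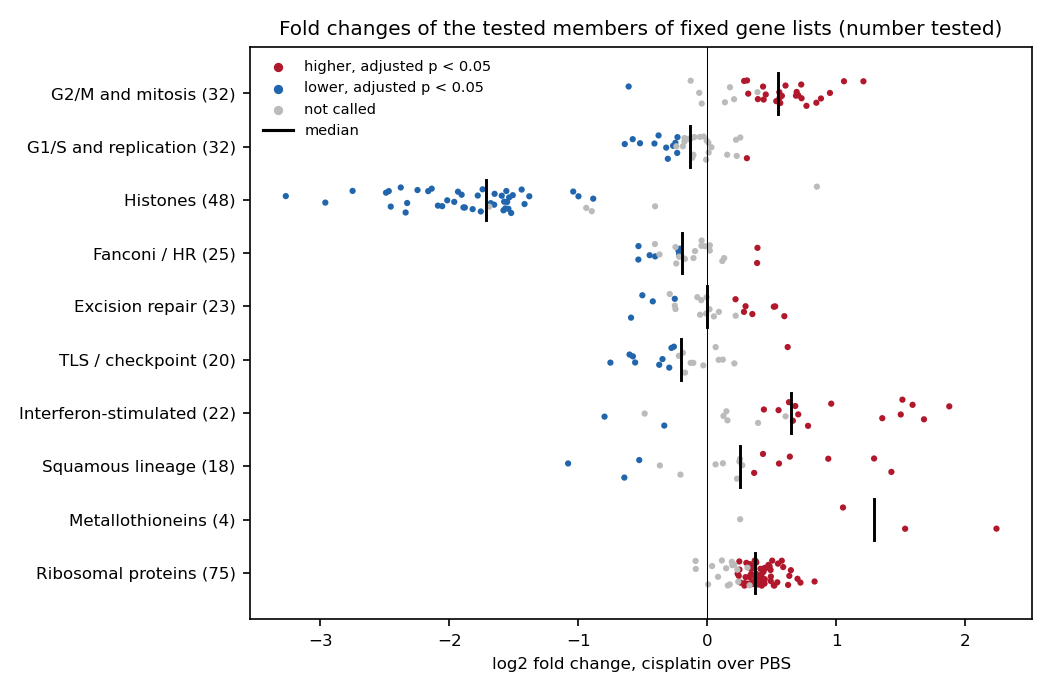
Log2 fold changes, cisplatin over PBS, of the tested members of 10 gene lists, each point 1 gene and each bar the list's median, with genes called higher in red and lower in blue. Histone genes lie around -1.72, while the G2/M and mitosis genes lie around 0.55.

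Interferon-stimulated genes were higher in 14 cases of 22 and lower in 2, with 15 and 3 adjusted over the list alone (camera adjusted p = 2.6e-04, and adjusted p = 0.351 with an estimated correlation). OAS1 went from 2.89 ± 0.211 to 10.5 ± 2.35 CPM, IFI6 from 5.92 ± 0.169 to 16.6 ± 3.16 CPM and IFI27 from 166 ± 25.1 to 262 ± 8.11 CPM. The mitochondrial kinase CMPK2 fell by 0.80 and the RNA sensor IFIH1 by 0.33, but DESeq2 called neither (adjusted p = 0.0737 and 0.122), and over the alternatives the adjusted p reached 0.0868 and 0.149. In edgeR, CMPK2 was not called without PBS replicate 2 (adjusted p = 0.0664), cisplatin replicate 1 (0.0529) or cisplatin replicate 3 (0.0772), nor IFIH1 without PBS replicate 3 (0.0848), cisplatin replicate 2 (0.0971) or cisplatin replicate 3 (0.0850). NF-kB target and cytokine genes gave 4 of 12 higher, including CCL2 (0.74) and NFKB2 (0.58), and 2 lower, SOD2 (-0.40) and NFKBIZ (-0.48), with 4 and 3 adjusted over the list alone (camera adjusted p = 0.206). The call of NFKBIZ was lost whichever of the 6 libraries was left out (edgeR adjusted p from 0.0615 to 0.152).

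Cytosolic ribosomal protein genes rose in 59 of 75 cases and the other 16 did not pass, with a median of 0.37 on the log2 scale (63 higher adjusted over the list alone; camera adjusted p = 2.1e-09). Their adjusted p = 0.575 with an estimated correlation, and after the length correction 39 were higher and 2 lower. RPS4X rose by 0.54, RPS12 by 0.59 and RPS29 by 0.70. These are short transcripts with many processed pseudogenes, so reads can be shared.

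Metallothionein genes, which encode metal-binding proteins, rose in 3 of 4 cases (also 3 adjusted over the list alone; camera adjusted p = 0.0425, and adjusted p = 0.503 with an estimated correlation). MT1X went from 6.46 ± 0.387 to 13.3 ± 2.81 CPM, and MT3 and MT1F, each under 2 CPM, rose by 2.24 and 1.53 on the log2 scale. Together the 4 tested genes went from 36.3 to 50.7 CPM, and the 1 that was not called held most of the CPM under PBS. The list was not called by camera without PBS replicate 3 (adjusted p = 0.0635) or without cisplatin replicate 3 (0.0624), and the adjusted p was as low as 0.00732 among the alternatives. Of the NRF2 target and glutathione genes, 13 of 29 rose and 6 fell (14 and 6 adjusted over the list alone; camera adjusted p = 0.147), and the length correction left 8 higher and 6 lower. Heme oxygenase HMOX1 rose by 0.89 and glutathione synthetase GSS by 0.51, whereas thioredoxin reductase TXNRD1 fell by 0.49 and GCLC, of the first step of glutathione synthesis, by 0.39. Platinum transporter and drug efflux genes were higher in 4 and lower in 2 of 13 cases, with the same counts adjusted over the list alone (camera adjusted p = 0.722; the median was -0.00134, the mean 0.08 and the test direction up). The copper chaperone ATOX1 rose by 0.59 and ABCC5 by 0.38.

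DNA repair lists moved in both directions. Fanconi anaemia and homologous recombination genes were lower in 7 and higher in 2 of 25 cases, with the same counts adjusted over the list alone (camera adjusted p = 0.0941), with 5 and 1 after the length correction and 4 and 2 with DESeq2. The nuclease FAN1 fell by 0.54 and RBBP8, which starts end resection, by 0.53, while FANCG rose by 0.39 and UBE2T by 0.38. Nucleotide excision repair genes were higher in 7 and lower in 4 of 23 cases (8 and 5 adjusted over the list alone; camera adjusted p = 0.943, with a median of -0.0069 under an upward test direction), and 3 and 5 after the length correction. The centrin CETN2 rose by 0.53, and RAD23B fell by 0.42. Translesion synthesis and checkpoint genes were lower in 9 and higher in 1 of 20 cases, with the same counts adjusted over the list alone (camera adjusted p = 0.0643). The checkpoint kinases ATR and ATM fell by 0.75 and 0.58, and CHEK2 rose by 0.62.

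The antiproliferative factor BTG2 went from 27.9 ± 1.03 to 72.7 ± 1.76 CPM and the oxidoreductase TP53I3 from 36.6 ± 2.64 to 65.6 ± 0.864 CPM, while ZMAT3 fell by 0.71 and the nuclease AEN by 0.48. Apoptosis genes were higher in 8 and lower in 5 of 27 cases, and likewise adjusted over the list alone (camera adjusted p = 0.231), but 7 and 1 after the length correction and 6 and 1 with DESeq2. The death receptor FAS rose by 1.70 from 0.926 ± 0.554 CPM, BIK by 1.21 and BMF by 0.86, and the inhibitor of apoptosis XIAP fell by 0.32. XIAP was not called by edgeR after the length correction (adjusted p = 0.776) or without PBS replicate 2 (0.0966), cisplatin replicate 1 (0.121) or cisplatin replicate 2 (0.0522), and its adjusted p was as low as 0.0132 among the alternatives. Integrated stress and unfolded protein response genes were lower in 9 and higher in 1 of 24 cases, with unchanged counts adjusted over the list alone (camera adjusted p = 0.134). The tRNA exporter XPOT fell by 0.82 and ATF4 by 0.31, and the chaperone CALR rose by 0.40.

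Squamous lineage genes, of which 18 of 28 listed were tested, rose in 7 cases and fell in 3, also when adjusted over the list alone (camera adjusted p = 0.165). TRIM29 went from 8.39 ± 1.27 to 20.4 ± 1.83 CPM, P-cadherin CDH3 rose by 0.64 and integrin ITGB4 by 0.55, while BCL11A fell by 1.08 and PITX1 by 0.53. Of 30 keratinocyte differentiation genes, 4 were tested and 0 were called by edgeR, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05, and 0 by DESeq2 or limma-voom (camera adjusted p = 0.733). Of these KRT10 had 10.4 and 11.2 CPM. Stem cell genes were higher in 3 and lower in 5 of 17 cases (4 and 5 adjusted over the list alone; camera adjusted p = 0.968), 4 and 3 after the length correction and 2 and 3 with DESeq2, with ALDH1A1 higher by 0.84 and NOTCH1 lower (-0.50). Epithelial-mesenchymal transition genes were higher in 9 and lower in 2 of 19 cases (9 and 3 adjusted over the list alone; camera adjusted p = 0.0904). The protease MMP2 rose by 0.95, vimentin (VIM) by 0.73 and TGFB1 by 0.94, and TGFB2 fell by 1.26, from 120 ± 6.42 to 50.3 ± 1.63 CPM.

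Notch and Wnt feedback genes were split, 7 higher and 7 lower of 24 (7 and 10 adjusted over the list alone; camera adjusted p = 0.784, with a mean of 0.02 against a median of -0.12 and a downward test direction). NKD1, a feedback inhibitor of Wnt signalling, fell from 2979 ± 167 to 1539 ± 53.8 CPM (log2 fold change -0.95, edgeR adjusted p = 7.6e-06), with a log2 fold change of -0.51 after the length correction, and ZNRF3 and RNF43, ligases that remove Wnt receptors, fell by 0.63 and 0.52. HEYL, NKD2 and APCDD1 of the same list rose by 0.67, 0.57 and 0.49. AP-1 and immediate early genes were lower in 6 and higher in 1 of 18 cases (7 and 1 adjusted over the list alone; camera adjusted p = 0.0574), with JUN lower (-0.62) and FOS higher (1.38, from 1.56 CPM). Camera called this list without PBS replicate 1 (adjusted p = 0.0329, the lowest among the alternatives, which reached 0.533). Mediator and transcriptional coactivator genes were lower in 10 and higher in 5 of 32 cases, as when adjusted over the list alone (camera adjusted p = 0.722; the median was 0.03, the mean -0.05 and the test direction down). The acetyltransferases EP300 and CREBBP fell by 0.83 and 0.64 and remained called after the length correction, by 0.57 and 0.37 lower, while the list then had 6 lower and 5 higher.

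Cholesterol synthesis genes were higher in 7 and lower in 4 of 24 cases (9 and 5 adjusted over the list alone; camera adjusted p = 0.231), with TM7SF2 higher by 0.91 and its regulator SREBF2 lower (-0.48). Hypoxia and glycolysis genes were higher in 4 and lower in 6 of 25 cases, with equal counts adjusted over the list alone (camera adjusted p = 0.968): VEGFA fell by 0.62 and SLC2A1, a glucose transporter, rose by 0.41. Mitochondrially encoded mRNAs, included as a sign of RNA quality, were higher in 1 and lower in 4 of 13 cases, as adjusted over the list alone (camera adjusted p = 0.505), led by MT-ND5 (-0.56).

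Of the markers of other cell types, those of fibroblasts rose in 3 of 5 tested cases (also 3 adjusted over the list alone; camera adjusted p = 0.0425, and adjusted p = 0.503 with an estimated correlation). COL1A1 went from 12.7 ± 2.43 to 22.3 ± 0.568 CPM, THY1 from 0.493 to 1.39 CPM and COL6A3 from 0.543 to 1.38 CPM, and DESeq2 did not call THY1 (adjusted p = 0.0685) or COL6A3 (0.117). In edgeR, THY1 was not called without PBS replicate 3 (adjusted p = 0.0528) or cisplatin replicate 1 (0.0652), nor COL6A3 without PBS replicate 1 (0.0722), PBS replicate 2 (0.0642) or cisplatin replicate 3 (0.160). The call of the fibroblast list was lost in camera without PBS replicate 1 (adjusted p = 0.0549) and without cisplatin replicate 2 (0.0506), with 0.00821 as the lowest among the alternatives. Neuroendocrine markers rose in 2 of 6 cases, UCHL1 (0.67) and CHGB (0.41), as adjusted over the list alone (2; camera adjusted p = 0.846, direction up with a median of -0.14 and a mean of 0.00223). Alveolar and adenocarcinoma markers rose in 2 and fell in 3 of 6 cases, as adjusted over the list alone (camera adjusted p = 0.730), with MUC1 higher by 1.26 and ABCA3 lower (-0.35). Leukocyte and endothelial markers had 1 gene higher, LYZ (1.84), and 1 lower, CD14 (-0.98), of 3 tested, all near or under 4 CPM, as adjusted over the list alone (camera adjusted p = 0.978, direction up with a median of -0.10 and a mean of 0.25). CD14 was not called whichever of the 6 libraries was left out (edgeR adjusted p from 0.0762 to 0.159).

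Cisplatin adducts block RNA polymerase, so fold changes were set against gene length. Across 14852 genes, which are not independent replicates, the log2 fold change had a Spearman correlation of -0.19 with genomic span and of -0.36 with transcript length. Median log2 fold changes ran from 0.09 in the quintile of genes with the shortest span to -0.16 in the longest, and from 0.20 to -0.24 by transcript length. In each library, the longest minus the shortest quintile by span, relative to the mean of the 6 libraries, was 0.04, 0.13 and 0.17 on the log2 scale under PBS and -0.10, -0.08 and -0.20 under cisplatin (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 libraries can give). After adjustment for transcript length the slope on log2 genomic span went from -0.0294 to 0.00411, and to 0.0146 with GC content added. Within transcript-length quintiles the Spearman correlation with span was 0.0473, -0.0328, -0.0303, -0.0627 and -0.142, from the shortest to the longest transcripts. Transcript length still varied within a quintile, from 3973 to 205012 bases in the longest. Within span quintiles the correlation with transcript length ran from -0.25 in the shortest to -0.36 in the longest. After the length correction the calls of UBE2T (edgeR adjusted p = 0.0884), NOTCH1 (0.205) and ABCA3 (0.348) were lost as well, while ZMAT3, SREBF2 and ATF4 kept theirs at -0.42, -0.31 and -0.48.

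**Figure D3:**
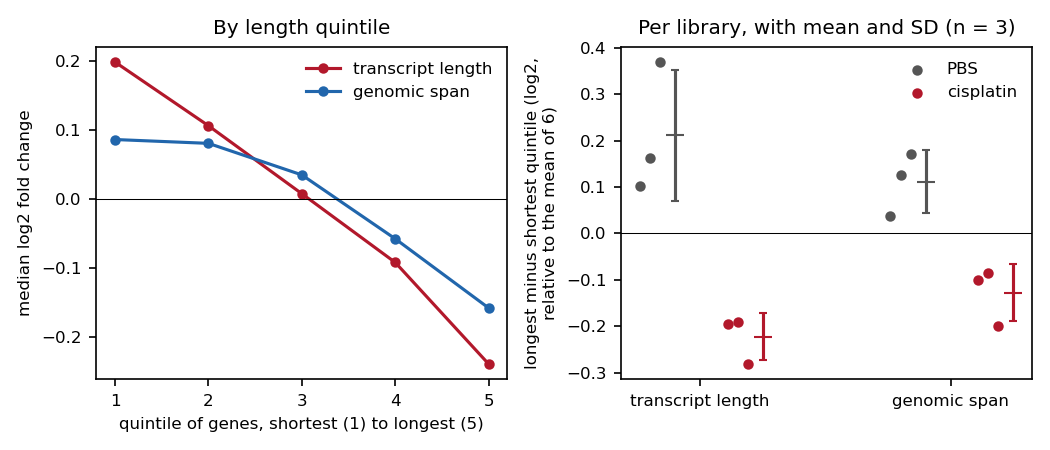
Left, median log2 fold change, cisplatin over PBS, by quintile of genes from shortest to longest, ranked by transcript length or by genomic span; right, the longest minus the shortest quintile in each library (log2, relative to the mean of the 6 libraries), with mean and SD. The medians go from 0.20 to -0.24 by transcript length, and the 3 cisplatin libraries lie below the 3 PBS libraries on both measures.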

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

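The corrections for transcript length and for length and GC content were chosen only after the results were seen; all other alternatives were planned. The count of 5752 genes lay between 4205 and 5283 with 1 library left out, at 4419 with DESeq2, 5202 with the length correction and 6066 with length and GC. It moved further under limma on log2(TPM + 1), to 2861 (1208 higher, 1653 lower), where the median of all genes shifted by -0.07, and under the test against 1.5-fold, to 481 (304 higher, 177 lower), which asks for a larger change. The count of genes changed at least 2-fold was 302 with the stricter filter, which still tests 11767 genes, and 248 on TPM, so it rests largely on genes with low counts. The length correction kept 4200 of the 5752 calls. Among named genes that were called, only XIAP and THY1 changed sign under an alternative run here: XIAP was at 0.04007 after the length and GC correction and THY1 at -0.0003286 on TPM; the cause was not tested. With length correction, MDM2 was at -0.2097 and ERCC1 at 0.1981, and with length and GC at -0.139 and 0.1126, none of them called, since the correction removes the trend these transcripts lie on. On TPM, MYC (-0.3039), ERCC1 (0.2454) and ABCC2 (0.07584) were not called, and besides THY1, 40 of the genes taken by the naming rule lost their call there, in the text also ATM, SLC2A1, COL1A1, BMF, FAN1, UBE2T, TK1, MCM4, XIAP, CALR, NOTCH1, NFKB2, CMPK2, IFIH1, APCDD1, HEYL, VEGFA, CHGB, ABCA3 and COL6A3. The cause was not tested. MYC was not called with total count scaling (-0.2335). Leaving out single libraries gave -0.5581 to -0.281 for MDM2, -0.4045 to -0.2096 for TP73, -0.3046 to -0.2004 for MYC and 0.2094 to 0.2939 for ABCC2; the cause was not tested. The labels do not say whether the replicate numbers pair the samples. Same-numbered deviations correlated at 0.07, 0.12 and -0.08, and not every sample correlated best with its own number. Pairing was thus neither shown nor excluded. With the replicate block 5819 genes were called, 5520 of them shared, and TP73 (-0.3053) passed. With an estimated correlation the adjusted p was 0.5031 for histones, metallothioneins and fibroblast markers, 0.4705 for G2/M, 0.351 for interferon and 0.5746 for ribosomal proteins, the last also at 0.06838 with fry. The fibroblast list had 0.05047 with upper quartile scaling, 0.05143 with total counts, 0.2132 with the stricter filter and 0.02243 to 0.05494 with 1 library left out. Metallothioneins had 0.05047 with upper quartile scaling, 0.2629 with the stricter filter, 0.05377 with length and GC and 0.00732 to 0.06347 with 1 library left out. Of the lists that camera did not call, it called epithelial-mesenchymal transition (0.006544) and G1/S, AP-1, NRF2, squamous and translesion genes (0.04868 each) without the low-count filter, G1/S genes after both corrections (0.04408 and 0.03196), and AP-1 (0.03779) and stress response genes (0.03735) with length and GC. Fry does not set a list against the other genes. It passed those lists too, and Fanconi, cholesterol, apoptosis, NF-kB and coactivator genes, with adjusted p from 0.01125 (stress response) to 0.04993 (coactivators). The counts of 1 or 2 called genes in one direction in the epithelial-mesenchymal transition, NF-kB, AP-1, translesion, platinum and mitochondrial lists each moved by 1 with the length correction. The difference between long and short genes, -0.2395 by span, was -0.4342 by effective length and -0.2722 to -0.2027 with 1 library left out. Depth limits the genes with the fewest counts, such as TP63, whose counts lie at or under the floor.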

Other observations

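The tests of fragment length and of S phase, the 3 gene lists and the symbol families below, and the corrections for transcript length and GC content, were chosen only after the results were seen; the other tests were planned. The bound for fragment length was also revised after its value was seen: under the first bound, overlapping ranges alone would have counted against fragment length.

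Large chromatin regulators were lower under cisplatin: 28 of 32 fell and the others did not pass (median log2 fold change -0.44; camera adjusted p = 1.0e-10 over these 3 lists, and adjusted p = 0.0261 with an estimated correlation). STAG1 of cohesin fell by 1.45, the methyltransferase KMT2D by 0.99 and the transcriptional repressor SPEN by 0.89. These are long transcripts, and after the length correction 21 were lower. STAG1, SPEN, SRCAP, KMT2D and ARID2 prompted the list. Without them 23 of 27 fell, and 16 after the length correction, where the median log2 fold change was -0.25 in place of -0.42. Their camera adjusted p, not corrected for length, was 0.0352 over these 3 lists with an estimated correlation. The camera p before the Benjamini-Hochberg adjustment was 0.0117, against 0.0121 for the planned interferon list. That planned list did not pass, at an adjusted p of 0.351 over all planned lists. These 3 lists were chosen after the results were seen, which leaving out the prompting genes does not undo. Their adjusted p therefore cannot be compared with those of the planned lists. Lysosomal genes went up, with 24 of 43 higher and 2 lower (camera adjusted p = 2.0e-06, and adjusted p = 0.0430 with an estimated correlation), among them the hydrolase CTSF (1.14), the growth factor precursor GRN (1.01) and the cholesterol carrier NPC2 (1.12). Without the 4 genes that prompted it, 20 of 39 were higher and 2 lower, and the adjusted p = 0.0745 with an estimated correlation no longer passed.

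Class I antigen presentation genes were higher in 9 and lower in 2 of 18 cases (camera adjusted p = 0.00181, and adjusted p = 0.0419 with an estimated correlation). B2M, the light chain of class I molecules, went from 233 ± 14.9 to 436 ± 9.56 CPM and HLA-B from 19.9 ± 0.597 to 39.7 ± 2.05 CPM (SD, n = 3), while the peptide transporter subunit TAP2 fell by 0.38. The list rests on the HLA genes, B2M, PSMB8 and PSMB9 that prompted it: without them 1 of 10 was higher and 2 were lower (camera adjusted p = 0.752). Among 158 families of gene symbols, zinc finger genes named ZNF were lower in 99 and higher in 21 of 413 cases (camera adjusted p = 0.0133, and adjusted p = 0.751 with an estimated correlation). After the length correction 71 were lower and 20 higher. Of all 15063 tested genes, 2901 were lower. Other families passed too, such as genes named MCM, lower in 8 of 10 cases (camera adjusted p = 0.0151, and adjusted p = 0.751 with an estimated correlation).

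Longer genes were lower under cisplatin. A single library does not account for it, since at least 67.31% of the slope on genomic span was kept with any 1 library left out. Adjustment for transcript length left -13.96% of that slope, so the pooled slope follows transcript length, as an effect of RNA fragmentation or size selection may do, but that test cannot separate such an effect from a biological one on long mRNAs. GC content, with 61.08% of the slope kept, and fragment length, with cisplatin fragments shorter by a difference of -9.903 bases and overlapping ranges, stay open. A polymerase block that grows with genomic span, the biological explanation the treatment gives, predicts a negative slope on span at a given transcript length. This explanation stays open. Over all genes that slope was 0.00411 ± 0.00223 (SE across genes), not negative, and 0.0146 with GC content added. The correlation with span was negative in 4 of 5 transcript-length quintiles and reached -0.142 in the longest. Transcript length varies within a quintile, from 3973 to 205012 bases in the longest, so these correlations cannot separate span from transcript length.

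Replication-dependent histone mRNAs were lower in the cisplatin libraries. Any poly(A) selection is not given, so the part of these mRNAs that the counts cover is not known. A change in that part cannot be told from a change in the whole. Loss of all RNAs without a poly(A) tail is argued against by 10 tested ones of classes fixed beforehand, with a median log2 fold change of 0.09076. Some were low, such as SCARNA12 and SNORD3B-1 at 0.87 and 0.94 CPM under PBS. The set leaves out tested genes annotated as rRNA (8, with 0 called), scRNA (1, called lower) and mitochondrial rRNA (2, called lower). Division of reads among near-identical copies is argued against by the summed histone CPM, whose lowest PBS library was 1.824-fold above the highest cisplatin library. Library size is argued against too, with a ratio of group means of 1.025. A lower share of cells in S phase may account for the loss and stays open, since the adjusted p of the G1/S and replication list was 0.05736. The same list passed after both corrections, at 0.0441 and 0.0320, but not with an estimated correlation (0.528).

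The count of 5752 called genes was reached by 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, and the highest of the others was 1 gene. With 10 splits the share cannot go under 0.05.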
